A study of Mus musculus with 2 samples.

How the data were processed

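RNA of single cells from subcutaneous CMT167R tumours was measured in 2 libraries, 1 from mice given solvent (control) and 1 from mice given the compound labelled PKCi. Per the labels, tumours were dissociated with an enzyme kit and passed through a 70 micrometre filter, and libraries were made with 10x 3' chemistry version 3.1 and sequenced on a NovaSeq 6000. The deposited files hold a count of unique molecular identifiers (UMIs) for each gene and barcode, made by the authors with Cell Ranger, version 7.0.0 per the file headers. The submitters' notes name GRCm38, Cell Ranger and Seurat and do not say what Seurat was used for. Each file lists 32285 genes, and reads were not used here.

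Barcodes with fewer than 500 detected genes (247 control, 200 PKCi) or over 20% mitochondrial UMIs (243 and 169) were left out. Doublets were called per library with Scrublet as run by scanpy, at an expected rate of 6%, which called 1.40% and 1.98% of the scored barcodes, and 88 and 143 further barcodes were removed. The kept cells had medians of 33043.5 and 29534 UMIs, 5734 and 5418 genes, and 1.65% and 1.49% mitochondrial UMIs. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, a graph of 15 neighbours was built on both libraries together without batch correction, and Leiden clusters were found at resolution 1.0. Mixed clusters were split once more at resolution 0.5.

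Clusters were named from marker lists. In each cluster the level of a marker was divided by its highest level over the clusters of at least 20 cells, and the mean over the markers of a class was its score. The best class gave the name when its score reached 0.35, at least 3 of its markers reached 50 CPM (UMIs per 1e6 UMIs of the sum) and Krt8 stayed under 250 CPM. In addition, the 10 genes with the highest ratio to the other cells could not hold more markers of any other class, or of red cells, than of its own. Clusters with a median under 10416 UMIs also needed at least 1 of its markers among those 10 genes. A cluster was split when a class of another lineage reached 0.4 or the best score lay between 0.3 and 0.7. Clusters with no class at that score, Krt8 at 250 CPM or more and a median of at least 10416 UMIs were called the main population, and the rest unnamed. Unnamed clusters thus include one scored as pericyte (10 and 11 cells) and one led by mast cell genes that came almost wholly from 1 PKCi barcode (16 and 29 cells), with Krt8 at 364.26 and 414.42 CPM, one scored as macrophage (58 and 78 cells) led by haemoglobin genes, and one with a median of 5661 UMIs (71 and 90 cells). These thresholds were set after seeing the data, while the marker lists, the filters, the gene lists, the comparisons and 14 alternatives (18 counting those run on both shares and gene levels for each) were fixed before the data were examined.

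The share of each class was given with exact Clopper-Pearson 95% intervals. For gene levels, UMIs were summed over the cells of a class in each library and divided by the total of the sum, with exact Poisson intervals and exact intervals for ratios; log2 ratios had 0.5 count added per sum. These intervals treat UMIs as independent and cover counting error only. Levels were compared in the 4 classes with at least 100 cells in each library. Their totals were 203756844 and 206284912 UMIs in the main population, 5578374 and 4260231 in monocyte-like, 3137969 and 6282385 in macrophage-like and 1786577 and 866221 in neutrophil-like cells. Genes had to have at least 50 UMIs over both libraries, 50 CPM in at least 1 of them and intervals that lay apart. They also had to reach 10% of their level in the class that expresses them most, since lower levels can come from free RNA. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, Y-linked and unnamed predicted genes and Xist were not named. The 12 genes with the highest and the 12 with the lowest ratio were named in the main population and monocyte-like cells, and 8 and 8 in the others. Where a library had 0 UMIs, the ratio was taken against a floor of 3 counts in that library's sum.

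For each of 33 gene lists, members with at least 20 UMIs over both libraries were taken, and the median log2 ratio was placed among 10000 random lists, each drawn from the 100 genes nearest in level to each member. Lists were described in a class only where Krt8 stayed under 10% of its level in the main population, at least 8 members were measured and under 50% of them could be free RNA. In addition the median had to lie outside the central 95%, or the list belonged to the aims of the series in the main population. This rule was set after seeing the data, and it removed all lists of neutrophil-like cells, of which 14 of 29 lay outside the central 95%. Cells with S phase or G2/M genes were counted by at least 3 genes of the list after thinning to 5000 UMIs. This left out 47 control and 197 PKCi cells of the main population, 71 and 133 monocyte-like and 8 and 38 macrophage-like cells. T-like cells were thinned to 2000 UMIs. Coordinates came from a GRCm38 annotation matched by gene identifier, for 96 of 96 genes.

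The method was tested on simulated data, with counts drawn from a Poisson distribution around the mean profile of a class and 200 genes changed in 1 of the simulated libraries. In the main population the intervals lay apart for 48 of 50 genes changed 0.25-fold and for 50 of 50 changed 0.5-fold, 2-fold and 4-fold, and for 24 of 3144 unchanged genes (0.763%). In macrophage-like cells they lay apart for 50, 48, 50 and 50 of 50 and for 15 of 3233 unchanged genes (0.464%). Of 200 random lists 8 lay outside the central 95% in each class. These draws hold no difference between animals, which 1 library per treatment leaves unmeasured.

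The alternatives were 10% mitochondrial UMIs, 200 genes per cell, doublets kept, resolutions 0.5 and 2.0, cells assigned by markers with no clusters, and the mean of the CPM of single cells. Further ones were median-of-ratios scaling, 3 counts added, list members with at least 100 or 1 UMI, no genes left out as possible free RNA, and at least 2 or 5 phase genes. After seeing the data, 5 more were added: clustering without 255 marker and named genes, the main population without cluster 0 or without cluster 10, gene levels at resolution 2.0, and subtraction of the main population profile at the level given by Krt8. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9, with random seed 0.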

Results

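Tumours grown under the skin of C57BL/6 mice from CMT167R cells, a line that the labels describe as resistant to anti-PD1 and whose parent CMT167 is a mouse lung carcinoma line, were profiled by droplet single-cell RNA sequencing. The control group was given solvent and the treated group a compound labelled PKCi at 3 mg/kg daily into the peritoneum. Tumours were taken when control tumours reached 400 mm3, at a time when the labels report a difference in volume between the groups. There was 1 library per treatment. The control library held 222641855 unique molecular identifiers (UMIs) and the PKCi library 229219749. After filtering, 6292 control cells with a median of 33043.5 UMIs and 7067 PKCi cells with a median of 29534 UMIs were kept. The title of the series asks about PKC signalling, the apoptosis inhibitor XIAP and an immunogenic change of resistant tumours. The comparisons therefore cover which cell classes made up each library and which genes and gene groups differed within each class. With 1 library per treatment no difference has a replicate check, no test between treatments was possible, and every interval given is a 95% interval that covers counting error only. The labels do not say how many mice contributed to a library.

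The largest group of cells, called the main population here, held 4914 control and 5366 PKCi cells. These cells carried Krt8, a keratin of simple epithelia, at 380 and 481 CPM (UMIs per 1e6 UMIs of the sum) in the control and PKCi libraries and Vim, the intermediate filament protein vimentin of mesenchymal cells, at 2793 and 2696 CPM. The epithelial adhesion gene Epcam was close to absent, at 0.00491 and 0.00485 CPM, and the leukocyte gene Ptprc (CD45) lay at 1.17 and 1.22 CPM against 352 and 379 CPM in monocyte-like cells. Krt18, another keratin of simple epithelia, lay at 6.84 CPM in the control library, and these clusters are given a neutral name. Xist, the X-inactivation RNA of female cells, lay at 1.23 and 0.940 CPM, against 50.8 CPM or more in all classes named below. It was at 357 and 490 CPM in monocyte-like and 451 and 154 CPM in fibroblast-like cells. Rhox5 stood at 540 and 469 CPM, against 55.2 and 35.9 CPM in monocyte-like cells. The Xist levels argue against host cells as the source of the main population. The other cells formed monocyte-like, macrophage-like, neutrophil-like, T-like, NK-like, dendritic-like, endothelial-like and fibroblast-like classes, and 2.53% of control and 3.00% of PKCi cells stayed unnamed.

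Macrophage-like cells made up a larger share of the PKCi library and neutrophil-like cells a smaller share. The macrophage-like share of kept cells was 2.495% (157 cells, exact interval 2.12 to 2.91) in the control and 6.74% (476 cells, 6.16 to 7.35) in the PKCi library, a ratio of 2.70 (2.25 to 3.25). Neutrophil-like cells took 4.70% (296 cells, 4.19 to 5.26) of control and 2.65% (187 cells, 2.28 to 3.05) of PKCi cells, a ratio of 0.562 (0.466 to 0.678). Monocyte-like cells were also less frequent in the PKCi library, at 7.24% (512 cells, 6.65 to 7.87) against 9.22% (580 cells, 8.51 to 9.96), a ratio of 0.786 (0.697 to 0.887). Monocyte-like and macrophage-like cells together took 11.7% (10.9 to 12.5) of control and 13.98% (13.2 to 14.8) of PKCi cells, a ratio of 1.19 (1.08 to 1.31). The main population took 78.1% (77.1 to 79.1) and 75.9% (74.9 to 76.9).

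Among the smaller classes, T-like cells took 1.03% (65 cells) of the control and 1.68% (119 cells) of the PKCi library, a ratio of 1.63 (1.19 to 2.24). Dendritic-like cells took 0.429% (27 cells) and 0.948% (67 cells), a ratio of 2.21 (1.39 to 3.59). The ratios of NK-like cells (1.26, 0.807 to 1.99), endothelial-like cells (1.34, 0.849 to 2.13) and fibroblast-like cells (0.965, 0.532 to 1.75) had intervals that included equal shares. As a share of the cells outside the main population, macrophage-like cells were 11.4% of the control and 28.0% of the PKCi library, neutrophil-like cells 21.5% and 10.99%, and monocyte-like cells 42.1% and 30.1%. Monocyte-like and macrophage-like cells together were 53.5% and 58.1% of the cells outside the main population, a ratio of 1.086 (0.986 to 1.196). That interval includes equal shares. When clustering was repeated without the marker genes and the named genes, the log2 ratio of shares was 1.22 for macrophage-like, -0.84 for neutrophil-like, -0.30 for monocyte-like and 1.07 for dendritic-like cells, while that of fibroblast-like cells moved to -1.38. At a coarser resolution the macrophage-like and monocyte-like clusters merged, with a log2 ratio of 0.26, and that of dendritic-like cells moved to 0.31 from 1.14. With cells assigned by markers alone the log2 ratio was 0.70 for macrophage-like and -0.72 for monocyte-like cells. That assignment put 4781 control and 5213 PKCi cells of the main population into the dendritic class, and its ratio for that class is not one of dendritic-like cells.

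**Figure D1:**
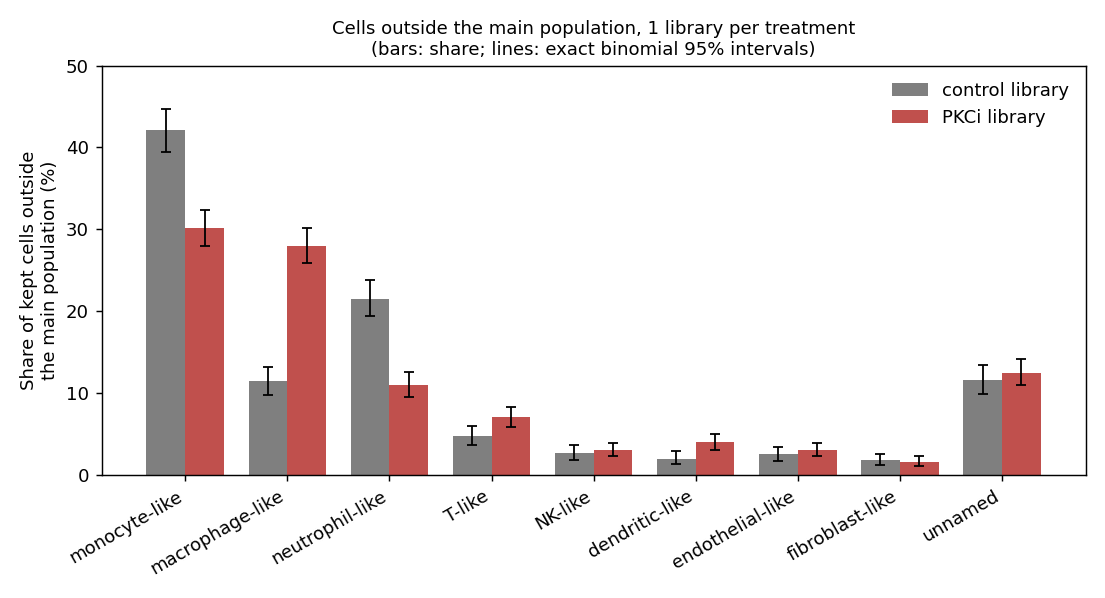
Share of each class among kept cells outside the main population (percent, linear axis) in the control library (grey) and the PKCi library (red); bars are shares and lines exact binomial 95% intervals. Macrophage-like cells stand at 11.4% in the control and 28.0% in the PKCi library, and neutrophil-like cells at 21.5% and 10.99%.

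Within the main population the libraries were close. Among the genes with the highest ratios were Csf2, Gdf15 and several immediate early genes, and among those with the lowest were Mt1, Mt2, Adm and Hnrnpa0. Of 3421 genes that passed the count and CPM minimum, 3242 were left after genes not named and possible free RNA were taken out. Of these, 3 were at least 2 times higher and 4 at least 2 times lower in the PKCi library, and 18 and 14 passed 1.5 times. Csf2 (ENSMUSG00000018916, protein-coding, chromosome 11, 54247271 to 54249667 on the minus strand of GRCm38), which encodes the myeloid growth factor GM-CSF, had the highest ratio. It stood at 27.9 CPM (27.2 to 28.7) in the control and 78.8 CPM (77.6 to 80.0) in the PKCi library, 2.82-fold higher (2.74 to 2.91). Gdf15, a stress-induced cytokine, was 2.22-fold higher and Sesn2, a stress-induced sestrin, 2.06-fold higher. Tfrc (chromosome 16, 32608920 to 32632794), the transferrin receptor through which cells take up iron, was at 45.8 and 86.7 CPM. The chemokine gene Cxcl10 was at 51.6 and 97.1 CPM, and the immediate early genes Fos (477 and 853 CPM), Fosb (217 and 362 CPM), Atf3 (148 and 253 CPM) and Zfp36 (117 and 194 CPM) were all higher. Tcim, Rgs3, which dampens G protein signalling, and Herpud1, a gene of the endoplasmic reticulum stress response, completed the 12 highest, each between 1.64-fold and 1.67-fold higher.

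The largest lower ratios in the main population belonged to the metallothioneins Mt1 (chromosome 8, 94179082 to 94180327) and Mt2 (chromosome 8, 94172664 to 94173568), neighbouring genes whose proteins bind zinc and copper. Mt1 was at 1085 CPM (1080 to 1089) in the control and 462 CPM (459 to 465) in the PKCi library, and Mt2 at 578 and 247 CPM. Adm, which encodes the hypoxia-induced peptide adrenomedullin, was at 67.2 and 31.2 CPM, and Bnip3, a hypoxia-induced mitophagy gene, at 54.6 and 28.4 CPM. Gclm, which encodes a subunit of the enzyme that starts glutathione synthesis, was at 122 and 72.5 CPM, Sod2, the mitochondrial superoxide dismutase, at 222 and 143 CPM, and Plin2, a lipid droplet coat gene, at 123 and 71.6 CPM. The RNA-binding protein gene Hnrnpa0 was at 330 and 164 CPM and Mbd2, which binds methylated DNA, at 114 and 58.4 CPM. Csnk2a2, a subunit of casein kinase (109 and 56.1 CPM), Purb (200 and 107 CPM) and Pcdh7, a protocadherin gene (74.4 and 43.4 CPM), completed the 12 lowest. Hnrnpa0 and Mbd2 were lower in every named class. In T-like cells they stood at 255 and 152 CPM and at 319 and 175 CPM. Csnk2a2 was lower in most classes, but not in dendritic-like (41 and 43.3 CPM) or fibroblast-like cells (41.5 and 45.6 CPM). Of the genes with the highest ratios, Csf2, Tfrc and Fos were higher in every named class. In T-like cells Csf2 stood at 24.4 and 40.7 CPM (11 and 26 UMIs), Tfrc at 37.7 and 84.5 CPM and Fos at 275 and 374 CPM. Such shared differences, lower or higher, are not specific to the main population, and without replicate libraries they cannot be told apart from a technical difference.

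Gene lists moved in both directions in the main population. The immediate early and AP-1 list had a median log2 ratio of 0.44 over 16 measured genes, at percentile 100 of 10000 random lists matched on expression. In it 4 genes were at least 1.5 times higher and 0 lower, and Jund stood at 621 and 895 CPM. The unfolded protein response list had a median of 0.21 over 15 genes (percentile 100), with 3 higher and 0 lower, namely Chac1 (5.33 and 9.68 CPM), Trib3 (23.1 and 39.7 CPM) and Herpud1. The hypoxia and glycolysis list had a median of -0.37 over 18 genes (percentile 0), with 0 higher and 4 lower; the glucose transporter Slc2a1 stood at 105 and 68.9 CPM and the glycolytic gene Pgk1 at 895 and 668 CPM. The mesenchymal list had a median of 0.12 (percentile 99.8), with Snai2 higher at 5.93 and 12.1 CPM and Lox, near the detection limit, lower. The dissociation stress list had a median of 0.13 (percentile 99.0) and was split, since Fos and Atf3 were higher while the heat shock genes Hspa1a (10.6 and 6.41 CPM) and Hspa1b (26.3 and 11.5 CPM) were lower.

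The described lists closest to the stated subject of the series differed little in these cells. None of the 11 measured PKC isoform genes was 1.5 times higher or lower, and their median log2 ratio was -0.15 (percentile 1.76), from Prkca at 85.7 and 71.1 CPM to Prkci at 23.9 and 24.4 CPM. Across the 8 IAP family genes and antagonists the median was 0.07 (percentile 95.3), with Xiap (chromosome X, 42059679 to 42109656) at 37.5 and 34.0 CPM. The MHC class I presentation list had a median of -0.04 over 21 genes (percentile 25.9), with B2m, the light chain of class I molecules, at 839 and 834 CPM. Immunogenic cell death genes had a median of -0.05 (percentile 26.7), with 0 of 13 higher and 3 lower, among them Hspa1a and Hspa1b, and calreticulin (Calr) at 373 and 361 CPM. The apoptosis list had a median of 0.03 over 19 genes (percentile 93.5). Type I interferon response genes belong to the same subject but fell under the free RNA rule, with 17 of 22 at such levels. Their median was 0.09 (percentile 97.15), with 2 higher and 0 lower. Small clusters of the main population had Isg15, a member of that list, among their leading genes. They held 31, 16, 3 and 2 control and 17, 13, 21 and 8 PKCi cells, so free RNA may not be the only source. Interferon gamma response genes fell under the same rule, with 14 of 19 at such levels. Their median went the other way, at -0.24 (percentile 0.175), with 2 higher and 2 lower. S phase and G2/M genes had medians of -0.05 (percentile 12.8) and -0.03 (percentile 46.9), with none of 22 genes in either list 1.5 times apart. In all, 13 of 33 lists lay outside the central 95% of their random lists in the main population. That count includes lists whose genes are mostly expressed far more in another class, which are not described. It cannot be set against 5%, which holds only for genes that vary independently. Genes of a list can vary together, and some lists share members.

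**Figure D2:**
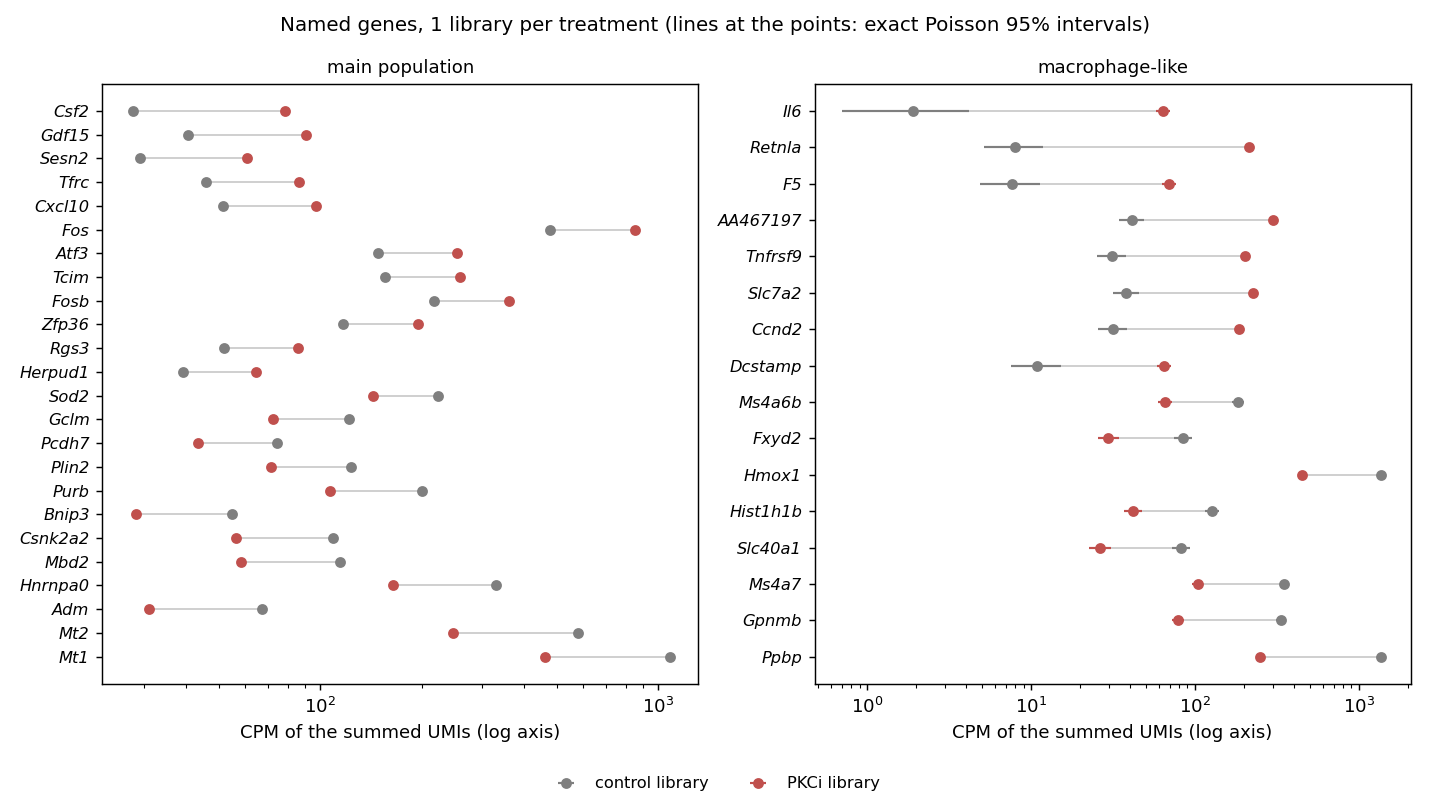
CPM of the summed UMIs (log axis) of the named genes in the main population (left) and in macrophage-like cells (right), control library in grey and PKCi library in red; lines at the points are exact Poisson 95% intervals and grey bars join the libraries. Csf2 stands at 27.9 and 78.8 CPM in the main population and Il6 at 1.91 and 64.0 CPM in macrophage-like cells.

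Macrophage-like cells of the PKCi library had more Il6, Retnla, Tnfrsf9 and Fn1 RNA and less Ppbp, Gpnmb and Hmox1 RNA. Of 3456 genes, 84 were at least 2 times higher and 34 at least 2 times lower. Il6 (chromosome 5, 30013114 to 30019981), the inflammatory cytokine interleukin 6, was at 1.91 CPM (6 UMIs, 0.702 to 4.16) in the control and 64.0 CPM (402 UMIs, 57.9 to 70.6) in the PKCi library, a ratio of 33.5 (15.2 to 91.7). Retnla, a marker of alternatively activated macrophages, was at 7.97 and 213 CPM, a ratio of 26.8 (18.1 to 41.6). Coagulation factor gene F5 (7.65 and 69.6 CPM), the costimulatory receptor gene Tnfrsf9 (31.2 and 201 CPM), and AA467197 (41.1 and 298 CPM) were among the 8 highest. The others were the cationic amino acid transporter gene Slc7a2 (37.9 and 227 CPM), the cyclin gene Ccnd2 (31.5 and 186 CPM) and the cell fusion gene Dcstamp (10.8 and 64.5 CPM). Among the 8 lowest, the platelet basic protein gene Ppbp was at 1369 and 248 CPM, Gpnmb at 333 and 79.0 CPM, the haem oxygenase gene Hmox1 (chromosome 8, 75093621 to 75100589) at 1366 and 453 CPM and the iron exporter gene Slc40a1 at 82.2 and 26.4 CPM. The histone gene Hist1h1b (128 and 42.0 CPM), Fxyd2 (84.8 and 29.6 CPM), Ms4a6b (183 and 65.7 CPM) and Ms4a7 (349 and 104 CPM), the last a marker used to name the class, were the others. With cells assigned by markers alone the Il6 log2 ratio was 1.17 in place of 4.95. In the control library Il6 (79.4 CPM), Tnfrsf9 (213 CPM) and Fn1 (1059 CPM) were higher in monocyte-like than in macrophage-like cells. So were Ppbp (2226 CPM) and Hmox1 (1516 CPM), which were lower in the PKCi library. Median depth of the macrophage-like class was 18498 and 12146.5 UMIs. Whether the class held more monocyte-like cells in the PKCi library was not tested.

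Proliferation genes were lower in macrophage-like cells of the PKCi library. G2/M genes had a median log2 ratio of -0.92, with 19 of 22 at least 1.5 times lower and 0 higher (percentile 0), such as Mki67 at 162 and 75.1 CPM and Top2a at 253 and 132 CPM. S phase genes had a median of -0.40 with 4 of 22 lower (percentile 0.01). The share of macrophage-like cells with at least 3 G2/M genes, after thinning to 5000 UMIs per cell, was 32.2% (48 of 149 cells, 24.8 to 40.4) in the control and 27.2% (119 of 438, 23.1 to 31.6) in the PKCi library. The difference of -5.05 percentage points had an interval from -14.2 to 3.59. Without thinning these shares were 68.8% and 54.4%. For S phase genes the thinned shares were 36.2% and 37.9%. Across the alternatives the G2/M median ran from -0.56 to -1.15, and with cells assigned by markers alone the S phase median was -0.05.

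Other lists in macrophage-like cells were mostly higher in the PKCi library. Immediate early and AP-1 genes had a median of 0.50 (percentile 100), with 6 of 16 higher and 0 lower, among them Fosl2 (86.7 and 190 CPM) and Junb (1485 and 2471 CPM). MHC class II genes had a median of 0.40 (percentile 99.2), with the invariant chain Cd74 at 1257.5 and 1898 CPM and 2 of 9 genes 1.5 times higher. Inflammatory macrophage genes had a median of 0.41 (percentile 99.89), with 5 of 12 higher, such as Ptgs2 (99.7 and 305 CPM) and Il1b (532 and 1046 CPM), and 2 lower, Fcgr1 and Cxcl9 (218 and 127 CPM). Interferon gamma response genes had a median of 0.33 (percentile 99.6; 3 of 17 higher, 2 lower), and NF-kB targets 0.29 (percentile 99.6; 2 of 15 higher). Neutrophil activation genes had 0.61 (percentile 99.96; 4 of 8 higher, 1 lower) and checkpoint and costimulatory ligands 0.30 (percentile 98.2), with Cd80 at 81.3 and 169 CPM. The mesenchymal list had a median of 0.37 (percentile 99.5), led by the fibronectin gene Fn1 at 618 and 2830 CPM, and a median of 0.08 once the main population profile was subtracted. Lower medians were found for lipid-associated macrophage genes (-0.41, percentile 0; 3 of 12 lower and 3 higher) and for necroptosis and pyroptosis genes (-0.28, percentile 0.99; 1 of 12 lower and 1 higher). Myeloid recruiting factors had -0.21 (percentile 2.38; 4 of 13 lower and 2 higher), such as the chemokine gene Ccl8 at 2769 and 1028 CPM. With cells assigned by markers alone the medians of inflammatory macrophage genes, NF-kB targets and neutrophil activation genes became -0.13, -0.03 and -0.20. The macrophage class made that way took in 251 control and 271 PKCi cells of the monocyte-like clusters.

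Monocyte-like cells of the PKCi library had less Cxcl5, Mmp8, Gpnmb and Hmox1 RNA and more Retnla and Fn1 RNA. In this class the median log2 ratio over 10845 genes was 0.13, so log2 values here are given relative to it, while CPM are as measured. Of 3111 genes, 49 were at least 2 times higher and 57 at least 2 times lower in CPM. These counts were 28 and 82 with median-of-ratios scaling and 119 and 24 at resolution 2.0. Retnla had 0 UMIs in the control library, up to 0.661 CPM, and 424 UMIs or 99.5 CPM in the PKCi library, at least 185-fold higher with the control sum set at a floor of 3 counts, while the exact interval of the ratio starts at 149.85. Fn1 (chromosome 1, 71585520 to 71653200) was at 1059 and 4506 CPM (1.96), and the carbonic anhydrase genes Car4 and Car6 at 3.76 and 94.8 CPM (4.49) and at 13.3 and 63.6 CPM (2.13). Ccnd2 (42.3 and 254 CPM), F5 (28.9 and 117 CPM), Plxdc2 (41.9 and 164 CPM), and the chemokine gene Cxcl14 (18.8 and 72.8 CPM) were also among the 12 highest. So were the receptor tyrosine kinase gene Axl (22.0 and 81.9 CPM), Ramp3 (22.4 and 78.6 CPM), Dcstamp (24.6 and 94.8 CPM) and Lyz1 (20.1 and 126 CPM), whose counts are uncertain because Lyz2 is nearly identical. Among the 12 lowest, the neutrophil chemokine gene Cxcl5 was at 92.7 and 4.46 CPM (-4.47), the collagenase gene Mmp8 at 327 and 25.1 CPM (-3.83), Gpnmb at 305 and 39.0 CPM (-3.09) and Hmox1 at 1516 and 324 CPM (-2.35). Mmp13 (416 and 72.1 CPM), the placental growth factor gene Pgf (88.9 and 16.2 CPM), Il7r (221 and 60.6 CPM), Cxcl9 (112 and 31.7 CPM), Nt5dc2 (70.5 and 20.7 CPM) and Ms4a7 (54.1 and 9.86 CPM) were also lower. Ppbp (2226 and 360 CPM) and Serpinb2 (692 and 122 CPM) met the same rule but were among the 10 genes that set the cluster apart from the others.

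The lists repeat this direction in monocyte-like cells. Relative to the class median, myeloid recruiting factors had a median log2 ratio of -0.95 (percentile 0), with 8 of 13 genes at least 1.5 times lower in CPM and 2 higher. Cxcl3 was at 6190 and 2511 CPM and Csf3, which encodes G-CSF, at 36.4 and 2.11 CPM. Lipid-associated macrophage genes had a median of -0.70 (percentile 0; 6 of 12 lower, 1 higher) and inflammatory macrophage genes -0.59 (percentile 0.01; 5 of 12 lower, 2 higher), with Tnf at 340 and 129 CPM and Nos2 at 62.7 and 20.7 CPM. Neutrophil activation genes had -0.70 (percentile 0.095; 4 of 9 lower, 1 higher). The neutrophil genes S100a8 (178 and 21.4 CPM) and S100a9 (195 and 7.51 CPM) were lower in these cells too, at levels that can come from free RNA, and with Ifitm1 they were not named for that reason. Of the 9 list members 0 lay at such levels. NF-kB targets had -0.47 (percentile 0; 5 of 15 lower, 1 higher), interferon gamma response genes -0.41 (percentile 0.04; 5 of 16 lower, 1 higher) and necroptosis and pyroptosis genes -0.52 (percentile 0.02; 2 of 12 lower). Unfolded protein response genes had -0.43 (percentile 0.01; 1 of 14 lower, 2 higher), and immunogenic cell death genes -0.41 (percentile 0.08; 0 of 13 lower, 1 higher). Hypoxia and glycolysis genes had -0.30 (percentile 0.41; 4 of 18 lower, 1 higher) and dissociation stress genes -0.36 (percentile 1.71; 2 of 9 lower). Higher medians were found for alternatively activated macrophage genes (0.23, percentile 99.7; 4 of 12 higher, 2 lower), with Ccl17 at 4.66 and 46.0 CPM and Il10 at 31.0 and 6.34 CPM, and for PKC isoforms (0.30, percentile 97.7; 2 of 9 higher), with Prkcb at 74.4 and 111 CPM.

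The makeup of the monocyte-like class differed between the libraries. At the finer clustering resolution, cluster 28 held 220 control and 128 PKCi cells of the class, cluster 30 held 249 and 53, and the part of cluster 34 that met no marker name held 58 and 274. With the class limited to cells that kept the name at that resolution, the medians turned positive for NF-kB targets (0.10), interferon gamma response genes (0.39), myeloid recruiting factors (0.25) and dissociation stress genes (0.25), all on the CPM scale. The log2 ratios of Mmp13, Serpinb2, Ms4a7 and Dcstamp changed sign.

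**Figure D3:**
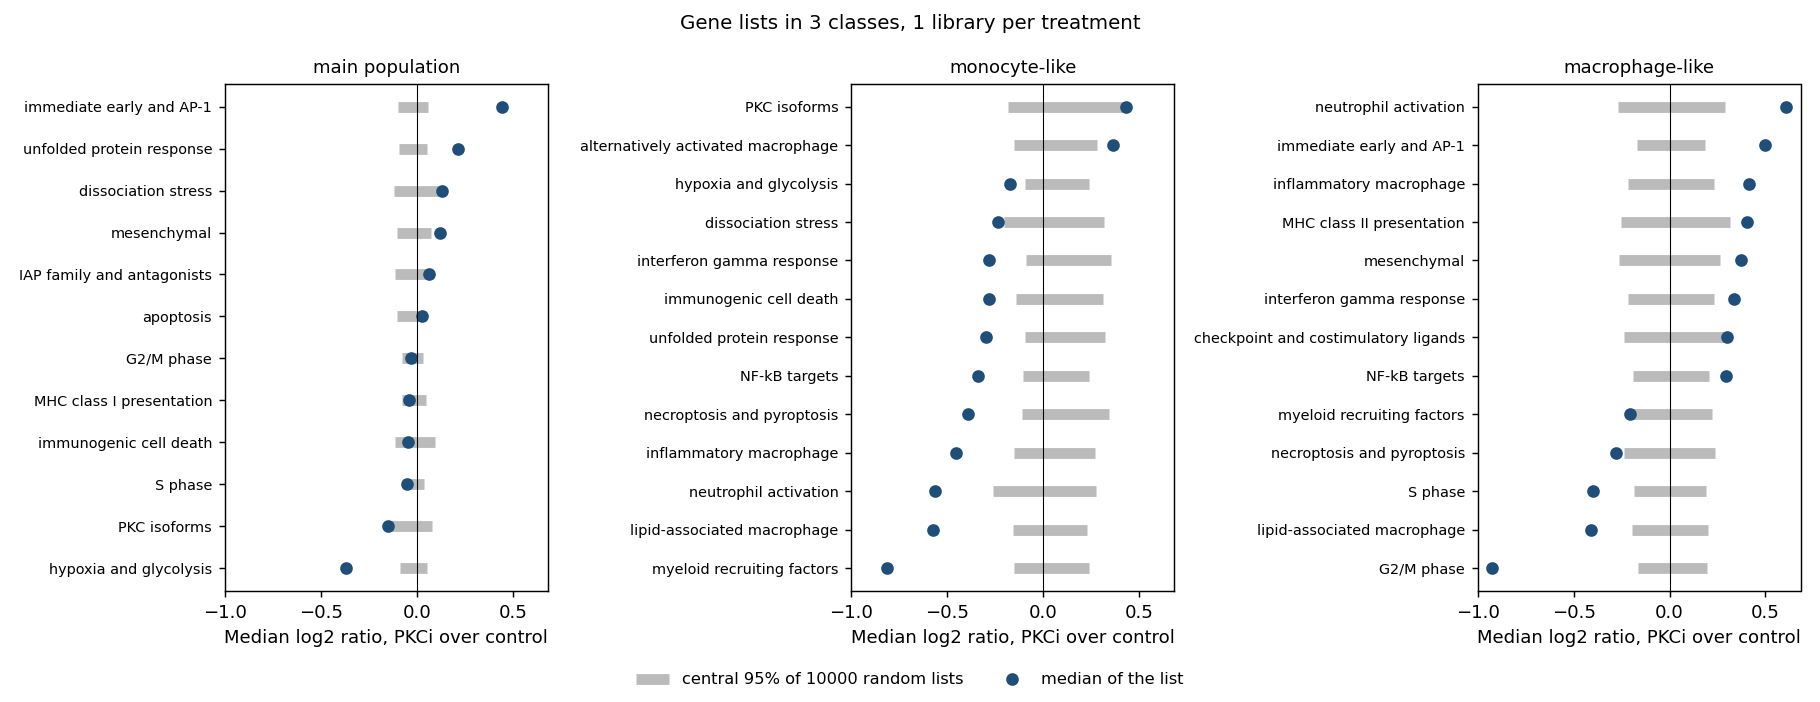
Median log2 ratio (PKCi over control, CPM scale) of the described gene lists in the main population, monocyte-like and macrophage-like cells; points are list medians and grey bars the central 95% of 10000 random lists matched on expression. Hypoxia and glycolysis genes stand at -0.37 in the main population and G2/M genes at -0.92 in macrophage-like cells, both left of their grey bars.

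In neutrophil-like cells the genes S100a8 and S100a9, which lead the cluster, were lower in the PKCi library, at 31044 and 6565 CPM and at 48761 and 13874 CPM. These genes alone do not separate a change within neutrophils from a lower neutrophil content of the barcodes. A lower content alone would lower all neutrophil genes by a like factor. The ratios of Ngp, Ly6g and Prok2 were at most 0.0298, 0.118 and 0.102, a far larger fall than that of S100a9. For these genes, picked for their low ratios, a lower content is argued against as the whole cause, and what else differed was not tested. The median log2 ratio over 8903 genes was 0.26 in this class, and Krt8 reached 33.0% of the main population's level in the control and 48.5% in the PKCi library. Median depth was 3408 and 2051 UMIs, and gene lists are not described for it. Ngp, a neutrophil granule protein gene, had 388 UMIs (217 CPM) in the control and 1 UMI in the PKCi library, a ratio of 188 with the control higher, and a ratio of PKCi to control between 0.000134 and 0.0298. Ly6g, the classic surface marker gene of mouse neutrophils, had 100 UMIs and 1 UMI. Nos2, the inducible nitric oxide synthase gene (chromosome 11, 78920787 to 78960254), had 169 UMIs (94.6 CPM) and 0 UMIs, at least 27.3-fold lower with the PKCi sum set at a floor of 3 counts, while the exact interval of the PKCi to control ratio ends at 0.0455. Stfa2 (306 and 1.15 CPM), Stfa3 (90.7 and 1.15 CPM) and Cstdc5 (246 and 6.93 CPM), members of a family of near-identical genes whose single values are uncertain, Prok2 (312 and 19.6 CPM) and Ifitm6 (452 and 32.3 CPM) were lower as well. Higher in the PKCi library were Cd80, a costimulatory ligand gene (107 and 513 CPM), the nuclear receptor gene Nr4a3 (20.7 and 121 CPM), and Jaml (40.3 and 180 CPM). Fgl2 (21.8 and 94.7 CPM), Lsmem1 (19.6 and 115 CPM), Mecom (15.7 and 75.0 CPM), Slc24a3 (11.2 and 58.9 CPM) and Tex14 (9.52 and 52.0 CPM) were higher too. In total 232 genes were at least 2 times higher and 92 at least 2 times lower, and with median-of-ratios scaling these counts were 78 and 163.

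Of the genes named by rank, 8 were named in both the monocyte-like and the macrophage-like class, Gpnmb, Hmox1, Ms4a7 and Ppbp as lower and Ccnd2, Dcstamp, F5 and Retnla as higher. Genes outside the ranks are not counted there, such as Fn1, which was higher in both classes.

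In T-like cells, thinned to 2000 UMIs, Foxp3, the regulatory T cell transcription factor gene, was detected in 20.6% of control cells (13 of 63, 11.5 to 32.7) and 7.41% of PKCi cells (8 of 108, 3.25 to 14.1), and unthinned in 36.9% (25.3 to 49.8) and 12.6% (7.23 to 19.9). In the main population, which should lack it, the thinned share was 0.0204% and 0.0573%, at median depths of 38198 and 35267.5 UMIs against 4745 and 4225 in T-like cells. Cd8a, a marker gene of cytotoxic T cells, was detected in 12.7% (5.65 to 23.5) and 22.2% (14.8 to 31.2) of thinned T-like cells and in 32.3% and 31.9% unthinned, so its order depended on thinning. Gzmb, a cytotoxic granule protease gene, was detected in 41.3% (29.0 to 54.4) and 25.9% (18.0 to 35.2), and Pdcd1, which encodes PD-1, in 20.6% and 17.6%. The thinned intervals of these genes overlapped between the libraries, and the unthinned ones of Foxp3 did not. In the main population the thinned share of cells with at least 3 S phase genes was 78.9% and 78.8%, and with at least 3 G2/M genes 72.3% and 71.3%. In monocyte-like cells these shares were 13.8% and 19.0% for S phase and 8.84% and 11.9% for G2/M.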

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

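The tests of the clustering, of barcodes with few genes and of host RNA, gene levels at resolution 2.0, the main population without cluster 10 and subtraction of the main population profile were chosen only after the result was seen, and the median log2 ratios compared between classes are on the CPM scale.

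Several lists had medians of opposite sign in 2 classes, and none of these differences was tested. Macrophage-like minus monocyte-like cells gave 0.63 for NF-kB targets (0.29 and -0.34), 0.87 for inflammatory macrophage genes (0.41 and -0.46), 0.62 for interferon gamma response genes (0.33 and -0.28) and 1.17 for neutrophil activation genes (0.61 and -0.57). Monocyte-like cells minus the main population gave 0.58 for PKC isoforms (0.43 and -0.15). The main population minus monocyte-like cells gave 0.36 for dissociation stress genes (0.13 and -0.23) and 0.51 for unfolded protein response genes (0.21 and -0.30). Of these 7 pairs 4 no longer had opposite signs at clustering resolution 2.0, where macrophage-like and monocyte-like medians were 0.0563 and 0.10 for NF-kB targets, 0.24 and 0.39 for interferon gamma response and -0.21 and -0.55 for neutrophil activation genes, and dissociation stress genes had 0.13 in the main population and 0.25 in monocyte-like cells. With cells assigned by markers, macrophage-like and monocyte-like medians were both negative for NF-kB targets (-0.0336 and -0.42), inflammatory macrophage genes (-0.13 and -0.39) and neutrophil activation genes (-0.20 and -0.36).

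Macrophage-like cells had a larger and neutrophil-like cells a smaller share in the PKCi library. Barcodes with at least 200 but under 500 genes are argued against as the whole cause of the lower neutrophil-like share. With all 73 that passed the other filters in the PKCi library counted as neutrophil-like and none of the 62 in the control library, the shares were 3.64% (3.22 to 4.10) and 4.66% (4.15 to 5.21). Loss of still shallower cells, of cells over the mitochondrial limit or of cells absent from the files cannot be told apart from the treatment. Thinning control neutrophil-like cells to the PKCi depth left 4.26% (267 cells, 3.78 to 4.79) of the control library, but that depth is the depth of cells that passed the gene minimum, so the value decides nothing. With cells assigned by markers and no clusters the log2 ratios were 0.70 and -0.86. Both lay on the side that the prediction set as going against a shift of cells between clusters. For neutrophil-like cells this argues against such a shift as the whole cause. For macrophage-like cells it cannot decide, since 0.70 is smaller than the 1.43 found with clusters. The macrophage class made that way also took in 251 control and 271 PKCi cells of the monocyte-like clusters. The same assignment failed for the main population, whose log2 ratio it moved to 0.61, but of the cells it called macrophage 11 control and 34 PKCi, and of those it called neutrophil 12 and 13, came from that population. It also rests on markers of which some, such as S100a8, S100a9 and Ms4a7, differed between the libraries. With the macrophage-like and monocyte-like clusters merged at resolution 0.5 the log2 ratio was 0.26. Among cells outside the main population, that of both classes together was 0.12 (-0.0201 to 0.259). A shift across their boundary therefore stays open for the macrophage-like share. The difference in tumour volume at harvest, differences between mice and differences in dissociation stay open and were not tested.

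Hypoxia and glycolysis genes were lower in the main population of the PKCi library. A cluster led by Adm, Mt1 and Mt2 held 251 control and 110 PKCi cells, but without it the median was -0.35, against -0.37 with it. Host RNA in these barcodes is argued against by S100a9, which stood at 0.0424% of its neutrophil-like level, and Lyz2, at 0.225% of its macrophage-like level. The difference in tumour volume at harvest stays open and was not tested.

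Immediate early and AP-1 genes were higher in the PKCi library in the main population and in macrophage-like cells. Free RNA of the main population is argued against for the macrophage-like cells, whose median was 0.52 after the main population profile was subtracted. Stress of the tissue dissociation cannot be told apart from the treatment: heat shock genes, which it would raise, had medians of -0.14 in the main population, -0.28 in monocyte-like, -0.07 in macrophage-like and -0.08 in neutrophil-like cells, but their members went both ways.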

How the results depend on the processing

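The alternatives chosen only after the result was seen are resolution 2.0 for gene levels, clustering without marker and named genes, the main population without cluster 0 or cluster 10, and subtraction of the main population profile. No paired analysis was possible because there is 1 library per treatment. All log2 values here are on the CPM scale, and the cause of a change was not tested except where given. Of 69 log2 ratios of shares under alternatives, 59 stayed close to the main value, 9 moved and 1 changed sign; close means inside the interval of the main ratio. For counts of genes at least 2 times apart these numbers were 70, 10 and 0 (close: within 1.5 times), for log2 ratios of named genes 557, 135 and 4 (inside the main interval), and for list medians 378, 21 and 8 (no farther from the main median than 50% of the width of the central 95% of random lists). The genes differed more than their counts: with cells assigned by markers, 22 of 49 higher and 35 of 57 lower monocyte-like genes and 42 of 84 higher and 11 of 34 lower macrophage-like genes were shared, and at resolution 2.0 16 of 49 and 8 of 57 monocyte-like genes. The 12 differences in cycling cells stayed within the intervals of the main values, but 3 changed sign: S phase in the main population (0.174 with 2 genes) and in macrophage-like cells (-4.80 with 5 genes), and G2/M in the main population (0.5002 with 5 genes). With no genes left out as possible free RNA, 24 of 24 named genes were shared in the main population, 20 of 24 in monocyte-like, 14 of 16 in macrophage-like and 16 of 16 in neutrophil-like cells.

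With cells assigned by markers and no clusters, log2 ratios of shares were 0.61 for the main population, -0.72 for monocyte-like, 0.70 for macrophage-like and -0.0203 for dendritic-like cells; nearly all of the main population went to the dendritic class, so neither ratio describes its class. At resolution 0.5 they were 0.26 for macrophage-like cells, whose cluster merged with the monocyte-like one, and 0.31 for dendritic-like cells; at resolution 2.0 they were -0.95 for monocyte-like cells and 0.47 for monocyte-like and macrophage-like cells together. Fibroblast-like cells moved to -1.26 with 200 genes per cell and to -1.38 when clustered without marker and named genes.

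The count of genes at least 2 times lower in the main population was 2 with the mean of single cells. In monocyte-like cells 119 genes were higher and 24 lower at resolution 2.0, and 28 were higher with median-of-ratios scaling. In neutrophil-like cells the higher genes numbered 111 with doublets kept, 357 with the mean of single cells, 78 with median-of-ratios scaling and 622 after subtraction, and the lower genes 163 with median-of-ratios scaling and 262 after subtraction.

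Monocyte-like cells at resolution 2.0 were those of cluster 28 alone, as the other cells of the class lost the name. There the medians were 0.10 for NF-kB targets, 0.39 for interferon gamma response, 0.25 for myeloid recruiting factors, 0.25 for dissociation stress, -0.15 for necroptosis and pyroptosis, -0.21 for inflammatory macrophage, -0.12 for lipid-associated macrophage and 1.56 for alternatively activated macrophage genes, the first 4 with changed sign. The log2 ratios of Dcstamp (-2.35), Mmp13 (0.50), Serpinb2 (0.58) and Ms4a7 (0.38) changed sign too. Interferon gamma response genes had -0.51 with 10% mitochondrial UMIs, -0.58 with 200 genes per cell and -0.57 with doublets kept. Lipid-associated macrophage genes had -0.81 with 10% mitochondrial UMIs, -0.80 with doublets kept and -0.32 with the mean of single cells, and neutrophil activation genes -0.85 with members of at least 1 UMI.

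Macrophage-like cells assigned by markers had medians of -0.0336 for NF-kB targets, -0.13 for inflammatory macrophage and -0.20 for neutrophil activation genes, all with changed sign, and of -0.0521 for S phase, -0.56 for G2/M and -0.45 for myeloid recruiting genes. At resolution 2.0 the median of neutrophil activation genes changed sign to -0.21, and the others were 0.0563 for NF-kB targets, 0.0352 for inflammatory macrophage, -0.64 for G2/M and -0.47 for myeloid recruiting genes. G2/M genes had -0.58 with the mean of single cells and -1.15 after subtraction, and the mesenchymal list 0.0820 after subtraction.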

Other observations

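No test in this part was chosen only after its result was seen, though the genes were picked because some of them stood out. No list of iron or haem genes was fixed, and these are single genes. Hmox1, which breaks down haem, was at 40.9 and 9.84 CPM in the main population of the control and PKCi libraries, 1516 and 324 CPM in monocyte-like, 1366 and 453 CPM in macrophage-like and 630 and 84.3 CPM in neutrophil-like cells. Its control level in the main population was 2.70% of the monocyte-like level, under the 10% limit for possible free RNA. Other host genes kept a far smaller part of their monocyte-like level there. In the control library Lyz2 stood at 31.0 against 9376 CPM and Ppbp at 7.23 against 2226 CPM. These values argue against free RNA of host cells as the whole source of Hmox1 in the main population. The ferritin gene Fth1, whose product stores iron, was at 5372 and 3479 CPM in the main population, and its log2 ratio was -1.09 in monocyte-like and -0.37 in macrophage-like cells. Tfrc, which brings iron into the cell, went the other way, at 45.8 and 86.7 CPM in the main population and 8.07 and 20.7 CPM in monocyte-like cells, with a log2 ratio of 0.38 in macrophage-like cells. Mt1 and Mt2 had log2 ratios of -0.27 and 0.04 in macrophage-like cells.

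A hypothesis for these genes is a wider difference in haem- and oxidant-responsive genes. Of a set of 13 others the median log2 ratio was -0.26 in the main population (percentile 0 of random lists), which may point that way there, and -0.0263 in macrophage-like cells (12 measured, percentile 37.1). The latter lay above the percentile that the prediction, written beforehand, set as going against the hypothesis in macrophage-like cells. Its members went both ways there, from Slc7a11 (1.33) to Blvrb (-0.83), a limit that the prediction did not name. The set had a median of -0.60 in monocyte-like cells, where no prediction was made.

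Mast cell genes in the PKCi library came almost wholly from 1 barcode. It held 643 of 672 UMIs of the protease gene Cma1, 470 of 514 of Mcpt4, 219 of 238 of Tpsb2 and 162 of 182 of Cpa3. The other 28, 44, 19 and 19 barcodes with these genes held at most 2 UMIs each, and the control library 2, 1, 2 and 2 UMIs in all. No mast cell share is given.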
